A study of Homo sapiens with 4 samples.

How the data were processed

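The series holds 4 chromatin immunoprecipitation (ChIP-seq) libraries from HEK293T cells, an established human embryonic kidney cell line, transfected for 1 day. The transfected vectors were an empty vector, a vector carrying the 3xHA tag alone, 3xHA-tagged wild-type EVI1 (EVI1-WT) and the 3xHA-tagged splice form called EVI1+18. EVI1 is a zinc finger transcription factor. Chromatin was digested with micrococcal nuclease, precipitated with an antibody against the HA tag and sheared before library preparation, per the labels' protocols. Peak lists of 2 libraries were used, EVI1-WT and EVI1+18, with 1 library per group. The empty vector and 3xHA libraries were not analysed here, so no HA precipitation from cells without EVI1 stands beside the values.

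Peaks were called on each library separately with MACS 2.0.10.20120913 at a q-value threshold of 0.05, per the file headers. Reads were demultiplexed with bcl2fastq and the build was hg19, per the submitters' processing notes. The path of the control reads names BWA, per the file headers, and the aligner's version and settings are not given in the sources used here. Both peak lists were called against the same control, an input library of mock cells with 29153787 tags after filtering, and the name of this control carries another experiment code than the ChIP libraries, per the file headers. At most 1 tag per position was kept, tags of 50 bp were extended to a fragment length of 58 bp in EVI1-WT and 60 bp in EVI1+18, and the larger data set was scaled to the smaller, per the file headers. With 1 tag per position and strand, a pileup cannot exceed 2 times the fragment length, which gives a ceiling of 116 fragments for EVI1-WT and 120 for EVI1+18.

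The deposited pileup is a signal, the number of fragments over the summit, and was a whole number at all 347 and 388 peaks. The deposited fold enrichment is a ratio of the summit pileup to the local background that MACS estimated from the control. The deposited p-value and q-value columns hold −log10 values of the caller. These values belong to each peak and were used to describe, rank or filter peaks within their own list. The exception is the pileup, which was compared between libraries at overlapping peaks after division by the number of tags kept. EVI1-WT had 30395422 tags, of which 28191547 were kept, and EVI1+18 had 29905815, of which 27908825 were kept. The ratio of kept tags was 1.01.

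Coordinates are 1-based hg19 positions as deposited. Peaks of the lists were called shared when they overlapped by at least 1 bp (bedtools 2.31.1). Shares of peaks carry exact Clopper-Pearson 95% intervals, and ratios of pileups carry exact conditional binomial 95% intervals. All intervals cover counting error only, since nothing here measures the spread between cultures. Intervals of shares also treat peaks as independent, which neighbouring peaks may not be. The 347 EVI1-WT and 388 EVI1+18 peaks fell into 222 and 248 regions when peaks less than 20 kb apart were joined. For the level of overlap that placement alone gives, the EVI1+18 peaks were placed at random 1000 times with a fixed seed, each on its own chromosome, up to the last peak end seen on that chromosome in either list. Because the lists share their control, local features of that control can add overlap, and the reads that a simulation of this would need were not used here. Quartiles of a list were formed by fold enrichment. Peaks less than 20 kb apart were joined into regions. The overlap step was tested on simulated lists of 400 peaks with EVI1-WT peak widths, of which 200 were planted as shared, and it recovered 200 with 0 false pairs.

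With 1 library per group no test between the conditions was possible, and no p-value was computed over peaks. The peaks named were chosen by a rule fixed before the data were examined. The rule takes, without an annotation of the build, the 5 peaks with the largest fold enrichment in each class (EVI1-WT only, EVI1+18 only, and shared, the last by the mean of the within-list percentiles of one-to-one pairs). Other named peaks and regions were chosen after their values were seen. Planned counts of EVI1 motifs, of promoter, exon and intron positions, and of genes near peaks, over lists of reported EVI1 targets, AP-1, haematopoietic, ETS, TGF-beta, splicing, ribosomal protein and histone genes, need an hg19 genome and annotation, which were not used here. A gene table of GRCh38.p14 served for names only and lists EVI1 as a synonym of MECOM on chromosome 3. Alternatives tried were other overlap rules, stricter thresholds, lists of equal length, chromosome subsets and the removal of regions. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.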

Results

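HA-tagged EVI1 was profiled by ChIP-seq in transiently transfected HEK293T cells to compare where the wild-type protein and the EVI1+18 splice form sit on chromatin. Wild-type EVI1 yielded 347 peaks and EVI1+18 yielded 388 peaks on the hg19 genome, from 28191547 and 27908825 tags kept after filtering. Each form was represented by 1 library, so differences between the lists have no replicate error and are given as counts with intervals for counting error. Peaks were narrow and mostly low. The median width was 97 bp in EVI1-WT (interquartile range 70 to 168) and 120 bp in EVI1+18 (interquartile range 81 to 193). The median fold enrichment over the input control was 7.12 in EVI1-WT (interquartile range 5.59 to 9.03) and 7.15 in EVI1+18 (interquartile range 5.82 to 8.56). The median summit pileup was 13 fragments in both. All peaks together covered 70.0 kb in EVI1-WT and 82.2 kb in EVI1+18. On the mitochondrial sequence alone, 1 EVI1-WT peak covered 16552 bp and 9 EVI1+18 peaks covered 15925 bp.

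The strongest signal in both lists lay in 1 region of chromosome 3, the chromosome that carries MECOM, the gene encoding EVI1. This signal may come from DNA of the transfected EVI1 construct, which is weighed under Other observations. Between positions 168802691 and 168845859, a span of 43.2 kb, each list held 12 peaks, and all 12 of each list overlapped a peak of the other. Their fold enrichment ranged from 25.9 to 69.3 in EVI1-WT, with a median of 55.9, and from 24.8 to 67.1 in EVI1+18, with a median of 46.0. The peaks were 90 to 1376 bp wide, and peaks covered 7.54% of the span in EVI1-WT and 7.64% in EVI1+18. The 5 shared peaks with the highest mean rank in both lists were all in this region. They started, in EVI1-WT, at positions 168812852 (fold 69.3 in EVI1-WT and 64.4 in EVI1+18), 168833165 (56.9 and 67.1), 168807783 (57.0 and 57.9), 168838837 (57.2 and 54.5) and 168810741 (58.5 and 38.1).

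At these 12 pairs the median pileup was 108.5 fragments in EVI1-WT and 106 in EVI1+18, that is 93.5% and 88.3% of the ceiling set by keeping 1 tag per position. The pileup ratio of EVI1-WT to EVI1+18 per kept tag had a median of 1.03 and ranged from 0.98 to 1.17. The ceiling compresses any difference there. The peak edges of the lists coincided within 5 bp at every edge of the 12 pairs except one. That edge was the high-coordinate end of the peak starting at 168810741 in EVI1-WT, which ended at 168810898 in EVI1-WT and at 168810918 in EVI1+18, 20 bp farther. At the 141 one-to-one pairs outside this region, the mitochondrial sequence and 4 further dense regions on chromosomes 1, 5 and 11, the larger of the start and end differences had a median of 54 bp, against 3 bp in the chromosome 3 region. In the dense regions this median was 16 bp at 13 pairs on chromosome 1 and 6 bp at 7 pairs on chromosomes 5 and 11.

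**Figure D1:**
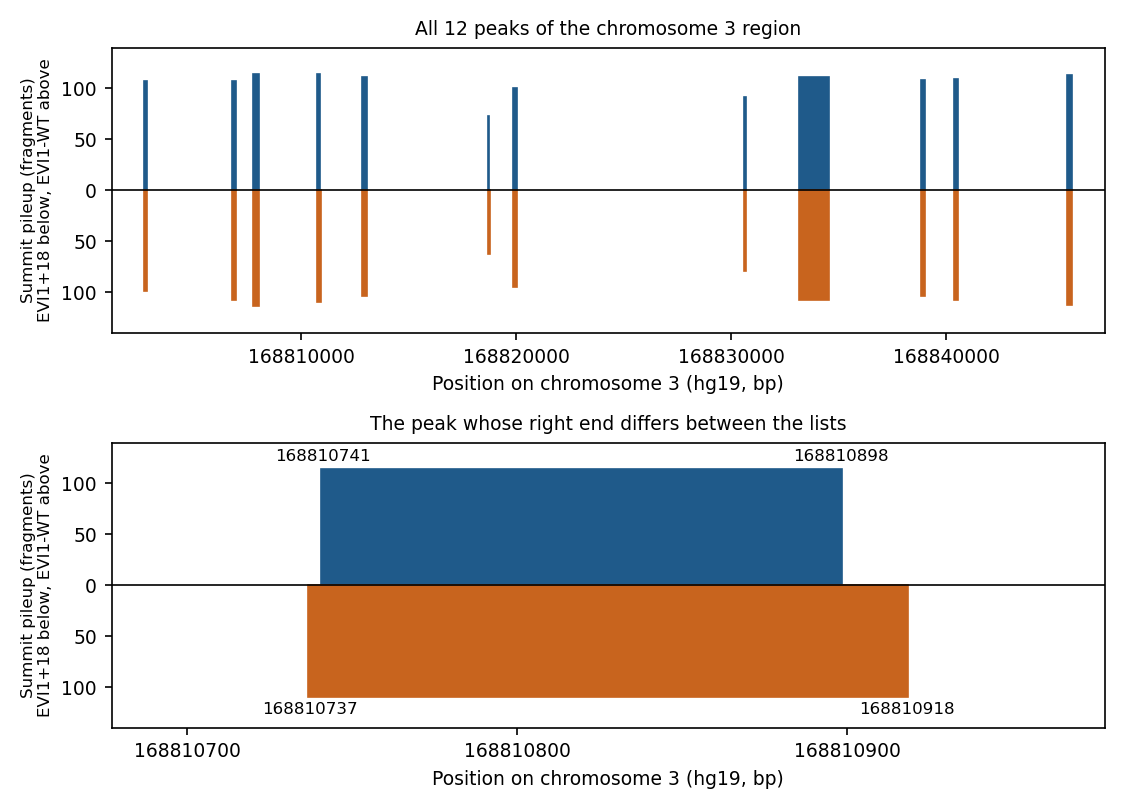
Peaks of EVI1-WT (bars upward) and EVI1+18 (bars downward) on chromosome 3, with the hg19 position in bp on the horizontal axis and the summit pileup in fragments as bar height; bar width is the peak width. The upper panel shows the 12 peaks of each list, at the same places, and the lower panel the peak that ends at 168810898 in EVI1-WT and at 168810918 in EVI1+18. These peaks may come from DNA of the transfected construct, and binding of the protein on the chromosome, in addition, cannot be told apart.

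Most peaks of each form had a counterpart in the other list. Of the EVI1-WT peaks, 216 of 347 (62.2%, 95% interval 56.9 to 67.4) overlapped an EVI1+18 peak, and of the EVI1+18 peaks, 215 of 388 (55.4%, 95% interval 50.3 to 60.4) overlapped an EVI1-WT peak. Random placement of the EVI1+18 peaks hit a median of 1 EVI1-WT peak (highest 3) and left a median of 9 EVI1+18 peaks in overlap (highest 10), 9 of which can lie on the mitochondrial sequence, where the EVI1-WT peak is almost as long as the sequence searched. Part of the excess may come from the control library that the lists share. Peaks that the HA precipitation gives without EVI1 would also be shared, and the libraries that could show them were not analysed here. Without the chromosome 3 region, the mitochondrial sequence and the 4 dense regions, 183 of 303 EVI1-WT peaks (60.4%) and 174 of 347 EVI1+18 peaks (50.1%) were shared. Requiring a reciprocal overlap of at least 50% lowered the shares to 40.1% and 35.8%, with 139 peaks of each list.

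Outside the chromosome 3 region, the highest-ranking one-to-one shared peaks, chosen after their values were seen, included one on chromosome 17 (78903552 to 78904532 in EVI1-WT). It had a pileup of 63 fragments in EVI1-WT and 78 in EVI1+18, a ratio per kept tag of 0.80 (95% interval 0.56 to 1.13). A peak on chromosome 12 (1231242 to 1231850 in EVI1-WT) had pileups of 36 and 46 and a ratio of 0.77 (95% interval 0.49 to 1.22). Pileups were 25 and 24 on chromosome 19 (10489160 to 10489672), 28 and 27 on chromosome 6 (20835596 to 20836058), 29 and 30 on chromosome 9 (25285877 to 25286068), and 24 and 20 on chromosome 11 (67965776 to 67966163). The ratios on chromosomes 19, 6, 9 and 11 were 1.03, 1.03, 0.96 and 1.19, and the intervals of all 6 of these ratios included 1. Over all 173 one-to-one pairs the median ratio of EVI1-WT to EVI1+18 was 0.99 (interquartile range 0.81 to 1.14). Over the 141 pairs outside the regions named above it was 0.89 (interquartile range 0.79 to 1.07), and EVI1-WT was the higher per kept tag at 40 of them. The highest ratio of the 173 pairs was at 149639333 to 149639420 on chromosome 2, where pileups of 49 and 25 gave 1.94 (95% interval 1.18 to 3.28). The lowest was at 158939089 to 158939156 on chromosome 7, where pileups of 8 and 16 gave 0.49 (95% interval 0.18 to 1.23). Both pairs were picked as extremes of the 173, and their intervals take no account of that choice. Division by the fragment length, which differed between the libraries, gave 1.02 over all pairs and 0.92 over the 141, and EVI1-WT was then the higher at 88 of the 173 and 56 of the 141, against 68 and 40 per kept tag alone. The 20 pairs that changed sides included all 18 with equal pileups.

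Peaks in 1 list only were narrower and weaker than shared peaks. The 131 peaks found only with EVI1-WT had a median width of 71 bp and a median fold enrichment of 6.21, against 138 bp and 7.87 for the shared EVI1-WT peaks. The 173 peaks found only with EVI1+18 had a median width of 89 bp and a median fold enrichment of 6.15, against 179 bp and 8.00 for the shared ones. In the lowest quartile of fold enrichment, 43.7% of EVI1-WT peaks (95% interval 33.1 to 54.7) and 34.0% of EVI1+18 peaks (95% interval 24.7 to 44.3) were shared. In the highest quartile, 86.2% (95% interval 77.1 to 92.7) and 89.7% (95% interval 81.9 to 94.9) were shared. A peak missing from a list was not called there at this depth, and its pileup in that library is not given in the list.

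**Figure D2:**
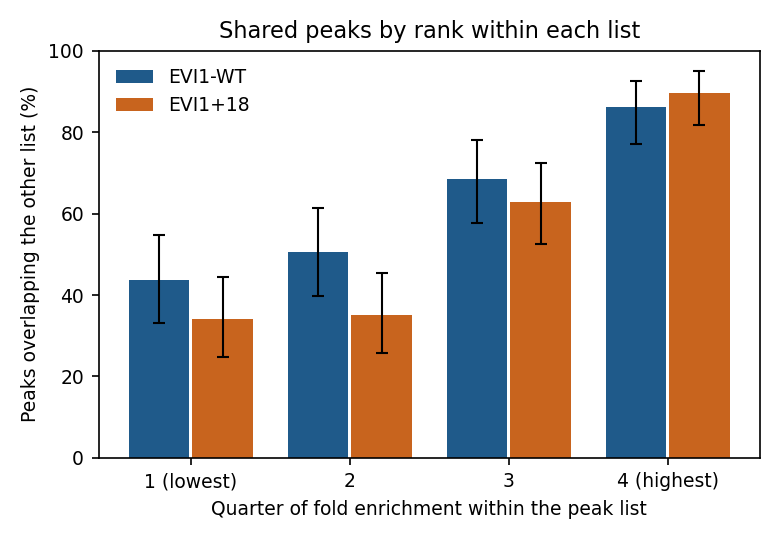
Share of peaks that overlap the other list, in percent, by quartile of fold enrichment within each list, for EVI1-WT and EVI1+18; error bars are exact Clopper-Pearson 95% intervals over peaks. The share is 43.7% and 34.0% in the lowest quartile and 86.2% and 89.7% in the highest.

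The strongest peaks of EVI1-WT without an EVI1+18 partner were 66 to 77 bp wide, against a median of 179 bp in the highest quartile of EVI1-WT. They lay on chromosome 7 at 45291596 to 45291661 (pileup 36, fold 18.3), chromosome 6 at 62284053 to 62284123 (pileup 33, fold 17.3), chromosome 11 at 10530759 to 10530835 (pileup 52, fold 14.3) and at 10530435 to 10530505 (pileup 29, fold 13.7), and chromosome 1 at 38077351 to 38077419 (pileup 25, fold 14.2). The nearest EVI1+18 peak was 6.38 Mb away on chromosome 7, 7.54 Mb on chromosome 6 and 9.84 Mb on chromosome 1. On chromosome 11 it was 1252 and 928 bp away, and both peaks lay in a dense region where EVI1-WT had 6 peaks and EVI1+18 had 1. The strongest peaks of EVI1+18 without an EVI1-WT partner lay on chromosome 9 at 66945220 to 66945305 (pileup 15, fold 9.44) and on chromosome 2 at 189183088 to 189183183 (pileup 17, fold 9.20), 87588952 to 87589042 (pileup 20, fold 9.004) and 90296018 to 90296193 (pileup 16, fold 8.69). On chromosomes 9 and 2, the peaks at 66945220 and 87588952 were 753 and 64 bp from an EVI1-WT peak. For the fifth place 6 peaks tied at a fold of 8.61, and the rule took the one with the lowest start position, on chromosome 17 at 26368486 to 26368652 (pileup 13).

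EVI1-WT had the higher pileup at dense groups of peaks in 4 further regions, which were chosen after the values were seen as regions with at least 4 EVI1-WT peaks and a median pileup of at least 25. On chromosome 1 at 564478 to 570289 both lists held 13 peaks, with a median pileup of 72 fragments in EVI1-WT and 52 in EVI1+18. On chromosome 5 at 134259839 to 134263703 EVI1-WT had 8 peaks and EVI1+18 had 5, with median pileups of 46 and 36. On chromosome 11 at 10529440 to 10531264 the counts were 6 and 1, and on chromosome 5 at 79945923 to 79947491 they were 4 and 1. At the 13 pairs on chromosome 1 the ratio of EVI1-WT to EVI1+18 per kept tag had a median of 1.36 and ranged from 1.05 to 1.69. At the 7 pairs of the other 3 regions it had a median of 1.59 and ranged from 1.43 to 1.78. Choosing the regions from EVI1-WT values favours ratios above 1. The same rule applied to the EVI1+18 list selected 2 of these regions, on chromosomes 1 and 5, where the ratio was above 1 at 18 of 18 pairs with a median of 1.40.

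**Figure D3:**
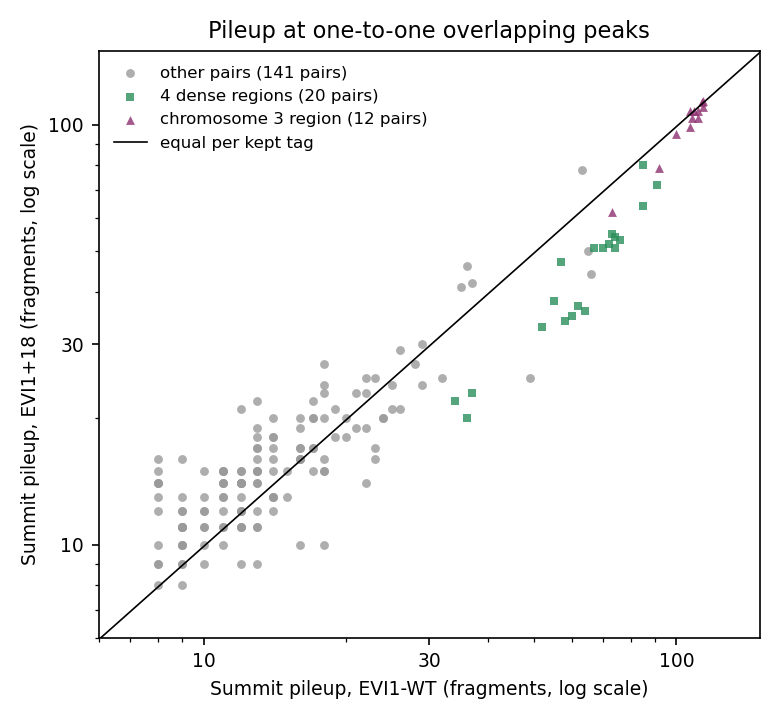
Summit pileup in fragments at the 173 one-to-one overlapping peaks, EVI1-WT on the horizontal and EVI1+18 on the vertical axis, both on log scales; each point is a pair, and the line marks equal pileup per kept tag. The 12 pairs of the chromosome 3 region sit near the line at the upper end, and the 20 pairs of the 4 dense regions lie below it.

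Outside the regions above, 30 groups of neighbouring peaks held at least 3 peaks in either list. EVI1+18 had more peaks in 17 of them, EVI1-WT had more in 9, and 4 held equal numbers. Numbers of peaks also depend on whether a stretch was called as 1 peak or split: by covered length, EVI1+18 was the higher in 24 groups and EVI1-WT in 6. Over the whole lists, too, EVI1+18 peaks were the more numerous (388 against 347) and the wider (median 120 against 97 bp), so these counts are not particular to the groups. In 5 of the 9 groups with more EVI1-WT peaks, EVI1+18 covered more bp. The groups named here were chosen after their values were seen. On chromosome 7 at 27161372 to 27204583 EVI1-WT had 3 peaks and EVI1+18 had 6. The strongest pair there, at 27203249 to 27203444 in EVI1-WT, had pileups of 18 and 23 and a ratio of 0.77 (95% interval 0.39 to 1.501). On chromosome 9 at 67351481 to 67354938 the counts were 1 and 6, on chromosome 2 at 87587462 to 87593166 they were 10 and 14, and on chromosome 20 at 61692669 to 61693440 they were 0 and 4. The 4 EVI1+18 peaks on chromosome 20 had a median pileup of 10 fragments. EVI1-WT had 4 peaks and EVI1+18 had 2 on chromosome X at 731470 to 741671, covering 371 and 245 bp. A group on chromosome Y at 681484 to 691540, about 50 kb lower, also held 4 and 2 peaks, covering 417 and 294 bp. The counts above hold both groups, though they may be 1 place counted on both chromosomes. Peaks also numbered 4 and 2 on chromosome 9 at 69735232 to 69736380, covering 296 and 557 bp. On chromosome 21 at 44048371 to 44050792, 4 and 2 peaks covered 1951 and 1975 bp.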

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

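Removal of the chromosome 3 region, the mitochondrial sequence or the 4 dense regions, ranking by q, and every alternative for the pileup ratio were chosen only after the data were seen; the other alternatives were chosen before. Of 49 alternative values for the main results, 38 stayed within the interval of the reported value (for a count, within 1.5 times) and 1 crossed to the other side of equality, the pileup ratio. The shared share moved with the overlap rule. A reciprocal overlap of 50% gave 40.1% of EVI1-WT and 35.8% of EVI1+18 peaks, and extension by 500 bp gave 74.1% and 70.1%. The upper 50% of each list by q raised the EVI1+18 share to 62.9%, and removal of all the regions named lowered it to 50.1%. The difference in shared share between the top and bottom quartile of EVI1+18 was 55.7 percentage points, and became 38.1 with extension and 75.3 when ranked by q. A −log10 q of at least 5 left 230 EVI1-WT peaks. The median pileup ratio was 0.99, reversed to 1.02 when divided by the fragment length, since that length differed between the libraries, and 0.89 without the regions named. Of the 30 alternatives for the 10 peaks named from 1 list only, 4 found a partner. The 50% reciprocal rule could find none for these peaks, since it is stricter than the 1 bp rule that left them unshared. The alternatives on motifs, positions relative to genes and gene lists were not run, since they need an hg19 genome and annotation. No paired analysis was possible because each group had 1 library, and no library could be left out for the same reason. The lowest pileups called were 8 fragments in EVI1-WT and 7 in EVI1+18, and sites below these levels were not detectable at this depth.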

Other observations

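The tests in this part were chosen after the results were seen, except the shared share by quartile of fold enrichment, which was planned. Peaks on the sex chromosomes came partly in pairs: of 9 EVI1-WT peaks on chromosome Y, 5 had a chromosome X summit 50 kb higher within 200 bp, and of 3 EVI1+18 peaks on chromosome Y, 2 did. On chromosome 12 at 54427265 to 54446180 EVI1-WT had 3 peaks covering 339 bp and EVI1+18 had 1 covering 283 bp. On chromosome 22 at 49893690 to 49894726, 1 EVI1-WT peak covered 355 bp with a pileup of 14 and overlapped 2 of 4 EVI1+18 peaks, which covered 439 bp with a median pileup of 11.

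The 12 narrow peaks on chromosome 3 may come from DNA of the transfected EVI1 construct, which the mock input control would lack. Reads of a cDNA would map to the exons of the chromosomal gene and stop at their borders. In this reading the EVI1+18 construct should lengthen 1 exon by about the number in its label, 18, and 1 edge did move by 20 bp, while no other edge of the 12 pairs moved by more than 5 bp. Peaks covered at most 7.64% of the region, which argues against extra copies of the whole region as the source of these narrow peaks. Copies that the input control also carried would raise the background as well, so the coverage cannot address them. Binding of the protein to chromosomal sites there, in addition, cannot be told apart. Edges differed by a median of 3 bp, against 54 bp at the 141 pairs outside the regions named. In the dense regions, however, the medians were 16 bp on chromosome 1 and 6 bp elsewhere, so closely matching edges were not particular to chromosome 3. Fixed nuclease cuts could also give coinciding edges, and exon borders in hg19 and the empty vector library were not used here.

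The higher pileup of EVI1-WT at the 4 dense regions was not a matter of depth. The regions were chosen from EVI1-WT values, which favours a ratio above 1, and over their 20 pairs the median ratio per kept tag was 1.43. The same rule applied to the EVI1+18 list alone, which favours the opposite, selected 2 of these regions, and there the ratio was above 1 at 18 of 18 pairs with a median of 1.40, while kept tags differed by a ratio of 1.01. A candidate explanation is more mitochondrial DNA in the EVI1-WT library, with part of its reads placed on nuclear copies of mitochondrial sequence. This cannot be told apart from an effect of the construct, because the highest summit on the mitochondrial sequence was near the ceiling in both, at 94.0% in EVI1-WT and 92.5% in EVI1+18, because the single EVI1-WT peak gives no value to set beside the lower EVI1+18 summits (down to 43.3%), and because no genome sequence was used to compare the regions. The difference between the EVI1 forms remains open and untested with 1 library each.

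Whether peaks found in 1 list only are weak peaks near the threshold of the caller stays open. The shared share rose from the bottom to the top quartile of fold enrichment by 42.5 percentage points in EVI1-WT and 55.7 in EVI1+18. Counting error at the observed summit pileups would lose 38.5 EVI1-WT peaks, against 131 unshared, and 41.5 EVI1+18 peaks, against 173. The pileups of called peaks overstate the mean, and peaks lost for their width are not in these numbers. Some unshared peaks had an exact lower limit of the pileup above the level needed for a call in the other library. These were 12 of 12 in the strongest quartile of EVI1-WT and 4 of 10 in that of EVI1+18. Over the whole lists they were 29 of 131 and 8 of 173. For the 12 this argues against counting error of the summit pileup, but not against loss of a narrow peak for its width. The 12 had a median width of 71 bp. The narrowest peaks called had the fragment length, 58 bp in EVI1-WT and 60 bp in EVI1+18. Of the 12 peaks, 5 lay in the 4 dense regions and 4 found a partner after extension by 500 bp. Loss of narrow peaks by counting error, variation between libraries beyond counting error and a difference between the EVI1 forms stay open. For the 5 in the dense regions, more mitochondrial DNA in the EVI1-WT library, the candidate given above, stays open as well.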
